A study of Mus musculus with 11 samples.

How the data were processed

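RNA of sorted CD24-negative, TCRβ-negative mouse thymocytes was measured in 11 libraries: 2 each of Bcl11b +/+, +/N440K and D/N440K at postnatal day 0, and 2 of Tcf7 +/+ and 3 of Tcf7 F/F:Vav1-Cre at postnatal day 7, with groups taken from the sample titles. Per the labels' protocols, cDNA was made by a modified RamDA-seq method, cut with Tn5 and amplified by PCR. The strand of counting is not stated.

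The count tables hold whole numbers per Ensembl gene that the authors deposited without normalization. Per the submitters' processing notes, fastp 0.20.0, STAR 2.7.3a, SAMtools 1.9, Picard 2.21.1 and HTSeq 0.11.2 were used on mm10 (GRCm38), and edgeR without a stated version. The annotation release is not stated. The Bcl11b table lists 53801 gene identifiers, 53706 of them in GENCODE M21, and the Tcf7 table lists 55471, 55230 of them in GENCODE M21, with 53402 in both tables. The authors' CPM tables hold the deposited counts divided by the library total over the listed genes times its TMM factor. Checked on each library, 100% of the CPM values gave back whole counts within 0.001. The genes listed there were the same 10910 and 12366 that filterByExpr kept here.

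Tests used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6. Counts of each table were filtered with filterByExpr (default minimum count of 10), normalised by TMM and fitted by edgeR's quasi-likelihood model with a coefficient per group, which left 3 residual degrees of freedom in each table. A gene was called at edgeR adjusted p (Benjamini-Hochberg) under 0.05, two-sided. The biological coefficient of variation was 0.0445 in the Bcl11b table and 0.122 in the Tcf7 table. The 4 comparisons were +/N440K and D/N440K with +/+, D/N440K with +/N440K, and Tcf7 F/F:Vav1-Cre with Tcf7 +/+. The comparisons with Bcl11b +/+ share its 2 libraries. Where a group had 0 counts, a bound on the fold was taken with a floor of 3 counts over the group, and with 1 to 3 counts a ratio with its exact 95% interval.

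Gene lists, 25 in number, were written before the data were examined, as were the comparisons, the rule for naming genes and most alternatives. They covered TCR signalling, pre-TCR and double-positive cells, T lineage factors, mature αβ, γδ, type 17 and ILC3, ILC2, NK and ILC1, cytotoxic granules, ILC precursors with PLZF, progenitors, Notch targets, B lineage, myeloid, dendritic and MHC II, mast and basophil, stroma, erythroid, DNA replication, G2 and mitosis, interferon response, immediate early genes, p53 and BCL2, mitochondrial RNA and ribosomal proteins. Lists with at least 5 tested genes were tested with camera (limma) at a preset correlation of 0.01, with an estimated correlation, and with fry. Mitochondrial RNA had 0 counts in every library of the Bcl11b table, so this list was tested in the Tcf7 table alone, as was the list of mast and basophil genes. Camera compares a list with all other genes, so a list can be called when none of its members is.

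The rule named Bcl11b, Bcl11a, Tcf7, Id2, Zbtb16, Gata3 and Cd24a among others in every comparison, the 6 largest called changes per direction among annotated genes of average log2 CPM 3 or more, and by p the first 4 members of each called list or the first of each other list. The report adds the called members of lists that moved both ways, profile genes, and Plxnd1 and Mtmr9, chosen after their values were seen. The results of some genes covered by the rule are not reported here. Shared calls were tested with Fisher's exact test, two-sided. Fold changes against a shared control were set against 50 simulations without change. The difference of the D/N440K and Tcf7 F/F:Vav1-Cre effects was tested in 1 edgeR model over all 11 libraries.

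Alternatives were RLE and upper-quartile normalization, no or a stricter filter (CPM of 5 in 2 libraries), no mitochondrial, ribosomal RNA and histone genes, DESeq2, limma-voom, limma on the authors' CPM (pseudocount 1), an absolute log2 fold change of at least 1, a replicate block, only the groups compared, and each library left out in turn. Where leaving out a library left a lone one in its group, that group was assumed to vary like the others of its table. The alternatives chosen after seeing the data were reads recovered from the authors' CPM, GC and length offsets, libraries with Y-linked reads only, sex as a term, and a crossed pairing. Tested on simulated data with 100 genes of each size changed, the edgeR model recovered 61 to 75% of 2-fold and 86 to 94% of 4-fold changes, with 3.77 to 7.36% of calls false. The simulations gave all groups of a table the same spread per gene. These shares may therefore not hold for the Tcf7 table, where the +/+ pair differed more than the other pairs. Total counts of 999381 to 1842717 per library, with 17544 to 20480 genes seen, limit precision for genes of low level. Replicate pairs were compared over genes with at least 20 reads: chi-square per degree of freedom was 1.16 in Bcl11b +/+, 1.42 in +/N440K and 1.13 in D/N440K, where 1 is counting error alone, 4.95 in Tcf7 +/+ and 1.69 to 2.15 in Tcf7 F/F:Vav1-Cre.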

Results

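The series measured RNA in CD24-negative, TCRβ-negative thymocytes, a sorted mouse thymus fraction that leaves out the bulk of developing T cells. A protocol modified from RamDA-seq, in which total RNA is copied with oligo(dT) and not-so-random primers and cut by Tn5, gave 11 libraries in 2 count tables. The Bcl11b table held postnatal day 0 thymocytes, with 2 libraries each of Bcl11b +/+, Bcl11b +/N440K and Bcl11b D/N440K. N440K is the changed residue of the Bcl11b protein, and the labels do not define D. The Tcf7 table held postnatal day 7 thymocytes, with 2 Tcf7 +/+ libraries and 3 libraries labelled Tcf7 F/F:Vav1-Cre, a floxed gene with a Cre recombinase driven by Vav1 in blood cells. Total counts per library were 999381 and 1210364 in Bcl11b +/+, 1246272 and 1040479 in +/N440K, and 1190180 and 1006353 in D/N440K. They were 1758096 and 1793027 in Tcf7 +/+, and 1273997, 1790439 and 1842717 in Tcf7 F/F:Vav1-Cre. Levels are normalised read counts (CPM), mean ± SD, with n = 2 per group and n = 3 in Tcf7 F/F:Vav1-Cre. Fold changes are log2 values from edgeR, ± SE. Each SE was derived from the edgeR fit, as the absolute fold change without shrinkage divided by the square root of the F statistic. Nothing in the labels says that replicates were separate animals. Each p-value of a single gene thus measures the spread between these libraries only, which may be technical. Camera at the preset correlation, Fisher's exact test and the shuffles compare genes with other genes. Their p-values do not measure the spread between libraries and can be very small with few libraries. Intervals and floors cover counting error only, since PCR reads carried no molecular identifiers.

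Feature genes of the sorted population were the first purpose in the design text. Levels of a fixed profile of genes were read from the +/+ libraries. No other population was measured, so no gene is shown to be a feature of this one. CPM is not corrected for transcript length, so genes are not ranked against each other. At postnatal day 0, Il2rb stood at 1507 ± 22 CPM, Cd3e at 502.5 ± 8.46, Zbtb16 at 376 ± 9.3, Trdc at 284 ± 4.84, Id2 at 278 ± 2.53 and Gata3 at 265.6 ± 16.4. Rag1 stood at 212.8 ± 4.34, Trbc1 at 202.9 ± 11.1, Trbc2 at 200.3 ± 6.13, Il7r at 162.1 ± 7.91, Fcer1g at 154.8 ± 1.86, Kit at 109.4 ± 17.4, Tcrg-C1 at 91.19 ± 0.195 and Klrb1c at 55.37 ± 7.41 CPM. Trac, the constant region of the TCR alpha chain, stood at 29.33 ± 6.26, and Ptcra, the pre-TCR alpha chain, at 5.56 ± 0.818. Cd24a, the gene of the sort marker, was at 11.34 ± 1.57 CPM. Among genes of other cell types, Lyz2 was at 82.28 ± 52.7, Cd79a at 5.367 ± 1.8 and Hba-a1 at 3.484 ± 3.75 CPM. At postnatal day 7, Il2rb stood at 880.6 ± 98.2 CPM, Cd3e at 385.2 ± 23.4, Rag1 at 363.2 ± 50.7, Il7r at 359.6 ± 55.9, Trdc at 321.5 ± 38.7, Zbtb16 at 289.4 ± 85.7, Id2 at 273.9 ± 35 and Gata3 at 188.8 ± 23.9. Lyz2 was at 213.3 ± 70.5, Cd24a at 10.14 ± 1.6 and Ptcra at 0.8454 ± 0.399 CPM there. The tables differ in age and processing, so their levels were not tested against each other.

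Bcl11b (ENSMUSG00000048251, GRCm38 chromosome 12, 107910403 to 108003602, minus strand) had 641.4 and 505.6 CPM in the Bcl11b +/+ libraries, 185.2 and 225 in +/N440K, and 151.6 and 203.6 in D/N440K. Bcl11a (ENSMUSG00000000861, chromosome 11, 24078056 to 24174123, plus strand) had 102.3 and 111.3 CPM in +/+, 47.33 and 53.3 in +/N440K, and 64.23 and 71.25 in D/N440K. Tcf7 (chromosome 11, 52252371 to 52283014, minus strand) had 552.2 and 593.5 CPM in Tcf7 +/+ and 846.7, 658.3 and 694.3 CPM in the libraries labelled Tcf7 F/F:Vav1-Cre. Counts per gene over all exons do not show whether any part of Tcf7 was deleted. In the Tcf7 table, Bcl11b had 324 and 342.7 CPM in +/+ and 209.4, 269 and 234.8 in Tcf7 F/F:Vav1-Cre, and Bcl11a had 260.9 and 167.4 against 193.3, 214.1 and 193.6. Bcl11a and Tcf7 each overlap other annotated genes, and the strand of counting is not stated. Among the 181 genes of the naming rule and profile, 85 overlap another annotated gene, Rag1, Gata3, Lef1, Satb1, Eomes, Cd3e and Trdc among them, so their counts may hold reads of a neighbour.

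**Figure D1:**
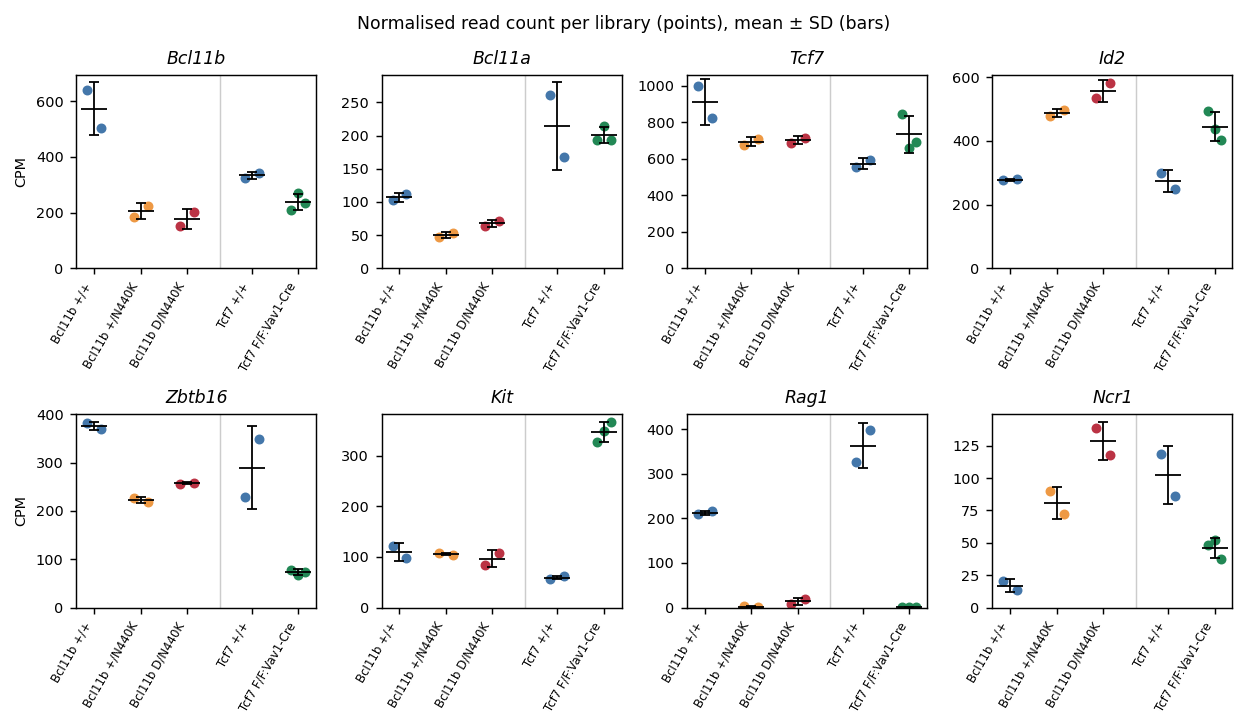
Normalised read count (CPM, vertical axis) per library for 8 genes in the 5 genotype groups, with points for libraries and bars for mean ± SD. Rag1 fell from 212.8 to 1.718 CPM in +/N440K and from 363.2 to 0.8317 CPM in Tcf7 F/F:Vav1-Cre, while Ncr1 rose from 16.87 to 128.4 CPM in D/N440K and Kit from 59.17 to 347.1 CPM in Tcf7 F/F:Vav1-Cre.

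The comparison of +/N440K with +/+ addressed the effect of the mutant allele beside a wild-type allele. Bcl11b fell from 573.5 ± 96 to 205.1 ± 28.1 CPM (log2 fold change -1.48 ± 0.11, edgeR adjusted p = 3.59e-13). Bcl11a fell by 1.10 on the log2 scale, with an SE of 0.164 (edgeR adjusted p = 4.05e-06). Rag1 and Arpp21, of the pre-TCR and double-positive list, fell further than Bcl11b. Rag1 went from 212.8 ± 4.34 to 1.718 ± 1.03 CPM (-6.81 ± 0.302, edgeR adjusted p = 2.67e-20), and Arpp21 from 128.5 ± 2.05 to 3.35 ± 3.34 (-5.12 ± 0.351, edgeR adjusted p = 2.58e-14). Of 12 tested genes of the pre-TCR and double-positive list, 11 fell and 1 was not past the test, Cd8b1 (-4.39) among those that fell. 11 fell when adjusted over the list alone (median -2.64, camera adjusted p = 1.05e-51, and camera adjusted p = 0.01017 with an estimated correlation). Of 18 TCR signalling genes 11 fell and 7 were not past the test, Cd3e (-0.71), Cd5 (-2.15), Cd6 (-2.30) and Cd247 (-1.13) among the former. 11 fell when adjusted over the list alone (median -0.50, camera adjusted p = 1.27e-13, and camera adjusted p = 0.01884 with an estimated correlation). Of 14 T lineage factors 10 fell and 4 were not past the test, with Lef1 at -1.79, Myb at -1.81 and Satb1 at -1.03. Adjusted over the list alone, 11 fell (median -0.42, camera adjusted p = 1.22e-21, and camera adjusted p = 0.0612 with an estimated correlation). Notch3, a Notch receptor, fell from 159.7 ± 2.75 to 27.99 ± 8.88 CPM (-2.48 ± 0.177). Tcf7 fell by 0.39 on the log2 scale (SE 0.077, edgeR adjusted p = 3e-04), a call lost without +/+ replicate 1 (-0.25, edgeR adjusted p = 0.07148). Cd24a had 25 counts in +/+ and 3 in +/N440K, a ratio of 8.55 (95% interval 2.61 to 44.2, edgeR adjusted p = 0.004876), and this call was lost without +/+ replicate 2 (edgeR adjusted p = 0.09218), +/N440K replicate 2 (edgeR adjusted p = 0.05784) and with DESeq2 (DESeq2 adjusted p = 0.2049). The log2 fold change of Cd24a moved from -2.99 to -6.63 without +/N440K replicate 1. Gata3 did not pass (-0.26 ± 0.101, edgeR adjusted p = 0.1139).

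Genes of γδ and type 17 cells fell in +/N440K, and genes of NK cells and ILC1 rose. Sox13, a factor of γδ cells that make IL-17, fell from 467.8 ± 104 to 18.83 ± 5.69 CPM (-4.59 ± 0.181, edgeR adjusted p = 1.11e-21), and Blk, a kinase of the same cells, from 258.6 ± 32.2 to 26.96 ± 2.35 (log2 fold change -3.26). Of 14 γδ genes 7 fell and 7 were not past the test, Sox4 (-2.17) and Maf (-0.76) among those that fell. 11 fell when adjusted over the list alone (median -0.70, camera adjusted p = 4.24e-27, and camera adjusted p = 0.01777 with an estimated correlation). Of 13 type 17 and ILC3 genes 2 rose, 7 fell and 4 were not past the test (adjusted over the list alone 2 rose and 9 fell). Il1r1 (-1.77), Il23r (-1.46), Il17re (-0.94), Nrp1 (-1.56), Ccr6 (-1.26) and Cxcr5 (-0.98) were among those that fell, and Ncr1 (2.30) and Ahr (0.45) rose. This list had a median of -0.98 with camera adjusted p = 6.36e-05, and camera adjusted p = 0.2188 with an estimated correlation. Ncr1, which encodes the NK receptor NKp46, rose from 16.87 ± 5.07 to 80.91 ± 12.5 CPM (2.30 ± 0.236, edgeR adjusted p = 1.77e-09). Eomes rose by 1.79 ± 0.238 and Tbx21 by 1.03 ± 0.116 on the log2 scale. Of 20 NK and ILC1 genes 17 rose and 3 were not past the test. All 20 rose when adjusted over the list alone (median 0.82, camera adjusted p = 4.24e-28, and camera adjusted p = 0.01172 with an estimated correlation). Of 10 cytotoxic granule genes 7 rose and 3 were not past the test, Gzma (1.08), Gzmb (0.99) and Serpinb6b (1.03) among them, and 7 rose when adjusted over the list alone. The median of that list was 0.77 (camera adjusted p = 3.97e-10, and camera adjusted p = 0.0612 with an estimated correlation). Id2 rose from 278 ± 2.53 to 487.3 ± 12.9 CPM (0.81 ± 0.0867, edgeR adjusted p = 4.66e-09), and Zbtb16 fell to 223.4 ± 6.05 CPM (-0.75 ± 0.0932, edgeR adjusted p = 1.26e-07).

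In the same comparison, 5 of 12 progenitor genes fell and 7 were not past the test, with Cd34 at -2.27, and adjusted over the list alone 1 rose and 5 fell (median -0.58, camera adjusted p = 0.0112). This call was lost without +/N440K replicate 1 (camera adjusted p = 0.05262), and the list had camera adjusted p = 0.1968 with an estimated correlation. Of 7 myeloid genes 2 rose and 5 were not past the test, S100a8 (2.96) and Lyz2 (0.81), and 3 rose when adjusted over the list alone (median 0.59, camera adjusted p = 0.02406). The myeloid call was lost without +/N440K replicate 2 (camera adjusted p = 0.08656), and the list had camera adjusted p = 0.1968 with an estimated correlation. Lyz2 itself was lost without +/+ replicate 1 (log2 fold change 0.33, edgeR adjusted p = 0.268, but 1.74 without +/+ replicate 2), and S100a8 without +/N440K replicate 2 (1.69, edgeR adjusted p = 0.1312). Lists that were not called still held changed members. In the mature αβ list (median -0.37, camera adjusted p = 0.1328), Zbtb7b (1.08), S1pr1 (0.40) and Klf2 (0.52) rose, and Il6ra (-0.59), Ccr7 (-2.13), Ccr4 (-1.69) and Trbc2 (-0.37) were among those that fell. In the ILC precursor list (median 0.19, camera adjusted p = 0.0655), Id2, Itgb7 (0.35), Il18rap (0.95), Il18r1 (0.86), Itga4 (0.65) and Zfp683 (0.87) rose, and Pdcd1 (-1.52), Ets1 (-0.23), Cxcr5, Zbtb16 and Tox2 (-1.46) fell. Among Notch targets Nrarp (1.63) and Dtx1 (0.67) rose and Tcf7 and Notch3 fell. The median of that list was 0.06 while its mean was -0.02 and its test pointed down (camera adjusted p = 0.226). Of the dendritic and MHC II genes Itgax (1.65) rose and Siglech (-0.59) fell (median -0.38, camera adjusted p = 0.4373), and of the p53 and BCL2 genes Bcl2l1 (0.42) and Bcl2l11 (0.32) rose and Trp53inp1 (-0.50) fell (median 0.17, camera adjusted p = 0.226). Bcl2l11 lost its call without +/+ replicate 1 (edgeR adjusted p = 0.1938) or +/N440K replicate 2 (edgeR adjusted p = 0.2362). Of 11 ILC2 genes 2 fell (median -0.36, camera adjusted p = 0.06177), and of 14 immediate early genes 3 rose, Fosl2 (0.73) among them (median 0.28, camera adjusted p = 0.05417). None of 19 DNA replication genes (median -0.10, camera adjusted p = 0.226), of 20 G2 and mitosis genes (median 0.10, camera adjusted p = 0.2028) or of 31 ribosomal protein genes (median 0.03, camera adjusted p = 0.3899) passed. Of 13 interferon response genes Usp18 alone fell (-0.69), and none when adjusted over the list alone (list median -0.13, camera adjusted p = 0.4373). Usp18 was not past the test without any 1 of the 4 libraries (edgeR adjusted p = 0.07068 to 0.226). Under 5 genes were tested of the B lineage (1 of 3 fell), stroma (2 of 4 fell) and erythroid (0 of 4) lists.

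Among called genes of average log2 CPM 3 or more, the largest rises in +/N440K were in Upp1 (2.268 ± 0.314 to 30.27 ± 14.9 CPM, log2 fold change 3.70 ± 0.523) and Syt8 (3 and 42 counts, ratio 13.6, interval 4.36 to 68.8). The largest falls outside the lists were in Endou (67 counts against 0, at least 22.9-fold lower, edgeR adjusted p = 9.24e-09), P2rx7 (121 counts against 3, ratio 41.4, interval 13.8 to 203) and Rapgef3 (65 counts against 1, ratio 66.7, interval 11.6 to 2670). edgeR called 1101 of 10910 tested genes, 523 higher and 578 lower, and the values of the groups did not overlap in 1100 of them, against 47.81% of all genes and a chance share of 33.33% for 2 libraries against 2. DESeq2 called 357 genes, and leaving out 1 library at a time gave 703 to 896 calls, the fewest without +/+ replicate 1. Of 20 tested lists, camera called 9, 3 up and 6 down, and 4 held with an estimated correlation (TCR signalling, pre-TCR and double-positive, γδ, and NK and ILC1).

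The comparison of D/N440K with +/+ addressed the mutant allele beside the allele labelled D. Bcl11b fell to 177.6 ± 36.7 CPM (-1.70 ± 0.114, edgeR adjusted p = 1.3e-14). Bcl11a fell to 67.74 ± 4.96 CPM (-0.67 ± 0.155, edgeR adjusted p = 0.001906), a call lost without +/+ replicate 2 (edgeR adjusted p = 0.05086), without D/N440K replicate 1 (edgeR adjusted p = 0.06005) and with DESeq2 (DESeq2 adjusted p = 0.1614). T-cell genes were again lower. Sox13 fell to 11.33 ± 2.69 CPM (-5.36 ± 0.203, edgeR adjusted p = 2.77e-22), Blk to 9.557 ± 3.44 (-4.70 ± 0.206) and Cd5 to 3.748 ± 0.456 (-4.15 ± 0.345). Of 12 pre-TCR and double-positive genes 11 fell and 1 was not past the test, Rag1 (-3.97), Arpp21 (-4.38, and -7.05 without D/N440K replicate 2) and Cd8a (-3.03) among those that fell. 11 fell when adjusted over the list alone (median -2.56, camera adjusted p = 1.27e-42, and camera adjusted p = 0.01589 with an estimated correlation). Of 18 TCR signalling genes 11 fell and 7 were not past the test, Cd3e (-1.11), Cd6 (-3.85) and Cd247 (-1.43) among those that fell. 12 fell when adjusted over the list alone (median -0.63, camera adjusted p = 5.52e-17, and camera adjusted p = 0.03066 with an estimated correlation). Of 14 γδ genes 10 fell and 4 were not past the test, Trdc (-1.30) and Maf (-1.18) among those that fell. 11 fell when adjusted over the list alone (median -1.23, camera adjusted p = 1.6e-34, and camera adjusted p = 0.01589 with an estimated correlation). Of 14 T lineage factors 10 fell and 4 were not past the test, Lef1 (-1.85), Myb (-1.77) and Satb1 (-1.35) among those that fell. 11 fell when adjusted over the list alone (median -0.36, camera adjusted p = 1.27e-19, and camera adjusted p = 0.08268 with an estimated correlation). Tcf7 fell by 0.37 on the log2 scale (edgeR adjusted p = 4.43e-04), a call lost without +/+ replicate 1 (-0.23, edgeR adjusted p = 0.09529). Gata3 did not pass (-0.23 ± 0.101, edgeR adjusted p = 0.1639). Cd24a fell by 2.25 on the log2 scale (edgeR adjusted p = 0.01857), a call lost without either +/+ library (edgeR adjusted p = 0.06147 and 0.1901) or D/N440K replicate 2 (edgeR adjusted p = 0.1651).

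Of 13 type 17 and ILC3 genes, 3 rose, 8 fell and 2 were not past the test in D/N440K, and 4 rose and 8 fell when adjusted over the list alone. Il23r (-2.93), Il1r1 (-2.40), Tnfsf11 (-2.16), Il17re (-1.91), Ccr6 (-1.33), Cxcr5 (-1.32) and Nrp1 (-1.08) were among those that fell, and Ncr1 (2.96), Lta (1.01) and Ahr (0.51) rose (median -1.32, camera adjusted p = 1.77e-05, and camera adjusted p = 0.1617 with an estimated correlation). Of 11 ILC2 genes 4 fell and 7 were not past the test, Hlf (-3.60), Ccr4 (-2.02), Ptgdr2 (-1.56) and Il17rb (-0.84), and 5 fell when adjusted over the list alone. Without D/N440K replicate 1 Hlf stood at -7.69 (edgeR adjusted p = 1.96e-05) and Il17rb at -1.39 (edgeR adjusted p = 5.57e-05), and Il17rb was lost without D/N440K replicate 2 (-0.49, edgeR adjusted p = 0.1289). That list had a median of -0.30 (camera adjusted p = 0.002067, median -0.17 without +/+ replicate 1, and camera adjusted p = 0.1122 with an estimated correlation). Ncr1 rose to 128.4 ± 14.6 CPM (2.96 ± 0.215, edgeR adjusted p = 1.05e-13), Eomes to 118 ± 33 (2.44 ± 0.218) and Tbx21 to 319.8 ± 35.7 (log2 fold change 1.16). Of 20 NK and ILC1 genes 19 rose, 19 also when adjusted over the list alone, and 1 was not past the test, Ccl4 (0.38). The list median was 0.94 (camera adjusted p = 8.32e-35, and camera adjusted p = 0.01589 with an estimated correlation). Of 10 cytotoxic granule genes 8 rose and 2 were not past the test, Gzma (1.32), Gzmb (1.11) and Gzmc (1.44) among those that rose. 9 rose when adjusted over the list alone (median 1.05, camera adjusted p = 3.39e-13, and camera adjusted p = 0.05739 with an estimated correlation). Of 7 myeloid genes 4 rose and 3 were not past the test, Lyz2 (1.29), Csf1r (1.17), S100a8 (2.56) and Fcgr3 (0.97). When adjusted over the list alone 4 rose (median 0.97, camera adjusted p = 0.002763, and camera adjusted p = 0.1122 with an estimated correlation). Lyz2 stood at 0.81 without +/+ replicate 1 and rose more without +/+ replicate 2. S100a8 was lost without D/N440K replicate 1 (edgeR adjusted p = 0.1794), and Fcgr3 without either +/+ library (edgeR adjusted p = 0.05425 and 0.06639) or D/N440K replicate 2 (edgeR adjusted p = 0.08486). Of 20 G2 and mitosis genes 5 rose and 15 were not past the test, and 7 rose when adjusted over the list alone (median 0.21, camera adjusted p = 0.005762, and camera adjusted p = 0.4083 with an estimated correlation). Mki67 rose by 0.32 ± 0.0734 on the log2 scale, a call lost without D/N440K replicate 2 (0.27, edgeR adjusted p = 0.06296). Id2 rose to 557.4 ± 33.7 CPM (1.00 ± 0.0857, edgeR adjusted p = 8.35e-12), and Zbtb16 fell to 257.3 ± 1.73 CPM (-0.55 ± 0.0917, edgeR adjusted p = 2.24e-05).

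Among lists not called between D/N440K and +/+, the ILC precursor list had a median and a mean of -0.07 while its test pointed up (camera adjusted p = 0.1683). Its Il18rap (1.21), Il18r1 (0.98), Zfp683 (1.03), Id2, Itga4 (0.61) and Itgb7 (0.34) rose, and Pdcd1 (-2.24), Tox2 (-1.02), Ets1 (-0.31), Cxcr5 and Zbtb16 fell. In the mature αβ list (median -0.36, camera adjusted p = 0.1683), Zbtb7b (1.15), Itm2a (1.23) and Klf2 (0.40) rose, and Ccr7 (-1.84), Ccr4, Trbc2 (-0.36) and Trac (-2.35) were among those that fell. In the progenitor list (median -0.18, camera adjusted p = 0.4364), Spi1 (1.14) and Meis1 (0.82) rose, and Bcl11a and Hmga2 (-2.13) fell. Of the Notch targets Nrarp (1.51) rose and Tcf7 and Notch3 (-2.44) fell, with a median of 0.06, a mean of -0.07 and a test that pointed down (camera adjusted p = 0.1265). Of the dendritic and MHC II genes Itgax (2.01) rose and Siglech (-0.57) fell, with a median of -0.05, a mean of 0.12 and a test that pointed up (camera adjusted p = 0.4487). The ribosomal protein list had no called member, with a median of 0.04, a mean of -0.01 and a test that pointed up (camera adjusted p = 0.8936). The interferon response list had none either, with a median of -0.03 and a test that pointed up (camera adjusted p = 0.8936). The immediate early list had 3 of 14 members higher (median 0.04, camera adjusted p = 0.1683). The p53 and BCL2 list had none of 12, but 6 higher and 1 lower when adjusted over the list alone (median 0.21, camera adjusted p = 0.1683). In the DNA replication list Mcm3 alone fell (-0.31), and none when adjusted over the list alone (list median -0.04, camera adjusted p = 0.4364). Without any 1 of the 4 libraries Mcm3 was not past the test (edgeR adjusted p = 0.05024 to 0.2932). Under 5 genes were tested of the B lineage (2 of 3 fell), stroma (2 of 4 fell) and erythroid lists (3 of 4 rose).

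The largest rises in D/N440K among called genes of average log2 CPM 3 or more were in Upp1 (to 44.71 ± 14.3 CPM, log2 fold change 4.24 ± 0.482) and Syt8 (ratio 14.9, interval 4.77 to 74.9). The largest falls outside the lists were in Zp1 (90 counts against 1, ratio 88.7, interval 15.5 to 3540) and Endou (67 counts against 1, ratio 66, interval 11.5 to 2650). edgeR called 1353 of 10910 genes, 665 higher and 688 lower, and the groups did not overlap in 1352 of them, against 50.98% of all genes and 33.33% by chance. DESeq2 called 528 genes, and 889 to 979 were called with 1 library left out, 889 without D/N440K replicate 1 and 892 without +/+ replicate 1. Camera called 10 of 20 lists, 4 up and 6 down, and the same 4 as in +/N440K held with an estimated correlation.

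The comparison of D/N440K with +/N440K addressed what the allele beside N440K adds. Few genes differed. Plcg1, a phospholipase downstream of the TCR, was lower in D/N440K, at 10.04 ± 4.51 against 57.64 ± 13.1 CPM (-2.57 ± 0.293, edgeR adjusted p = 5.05e-07), after 158.6 ± 11.7 CPM in +/+. It kept its call in every alternative run. Trdc (-0.70 ± 0.125, edgeR adjusted p = 0.002147) was lower but not past the test without +/N440K replicate 1 (edgeR adjusted p = 0.08353) or D/N440K replicate 1 (edgeR adjusted p = 0.06656). Ptgdr2 (-1.20 ± 0.199, edgeR adjusted p = 8.35e-04) lost its call without D/N440K replicate 1 (edgeR adjusted p = 0.06629), and Hlf (-3.12 ± 0.616, edgeR adjusted p = 0.00506) lost it without D/N440K replicate 2 (edgeR adjusted p = 0.1394) and stood at -7.21 without D/N440K replicate 1 (edgeR adjusted p = 0.004985). With DESeq2 these 3 were not past the test (DESeq2 adjusted p = 0.1515 to 0.3308). Rag1 was higher in D/N440K (13.95 ± 7.62 against 1.718 ± 1.03 CPM, edgeR adjusted p = 0.01423), as was Ncr1 (0.66, edgeR adjusted p = 0.02522), and Cd5 (-2.00), Cd8a (-1.15), Il17re (-0.97) and Cd3e (-0.39) were lower. These calls were lost with DESeq2 and with single libraries left out: Rag1 without +/N440K replicate 2 (edgeR adjusted p = 0.1215) or D/N440K replicate 2 (edgeR adjusted p = 0.3843), Ncr1 without any but +/N440K replicate 1 (edgeR adjusted p up to 0.5052), and Cd5 (edgeR adjusted p = 0.09819 to 0.355) and Cd3e (edgeR adjusted p = 0.06611 to 0.2867) without any of the 4. Hemoglobin genes were higher in D/N440K. Hbb-bs stood at 52.91 ± 5.78 against 6.206 ± 7.38 CPM (2.96 ± 0.441, edgeR adjusted p = 1.37e-04) and at 18.76 ± 18.3 in +/+. This call was lost with DESeq2 (DESeq2 adjusted p = 1), and the change was 5.58 without +/N440K replicate 1 (edgeR adjusted p = 6.76e-07). Hba-a2 had 31 counts against 3 (ratio 10.8, interval 3.36 to 55), lost without +/N440K replicate 2 (edgeR adjusted p = 0.09885) or D/N440K replicate 1 (edgeR adjusted p = 0.09155), and with DESeq2 (DESeq2 adjusted p = 1), and its log2 fold change moved from 3.32 to 6.96 without +/N440K replicate 1. Bcl11b (-0.21 ± 0.133, edgeR adjusted p = 0.7864), Bcl11a (0.43 ± 0.182, edgeR adjusted p = 0.4896), Tcf7 (0.02, edgeR adjusted p = 0.9859), Id2 (0.19, edgeR adjusted p = 0.4626), Zbtb16 (0.20, edgeR adjusted p = 0.636) and Gata3 (0.03, edgeR adjusted p = 0.9847) did not pass.

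By list, the shift between the mutant genotypes was small. Of 14 γδ genes 2 fell and 12 were not past the test, and 6 fell when adjusted over the list alone (median -0.32, camera adjusted p = 3.07e-07, and camera adjusted p = 0.1824 with an estimated correlation). Of 20 NK and ILC1 genes 1 rose, Ncr1, and 3 rose when adjusted over the list alone (median 0.19, camera adjusted p = 5.73e-06, and camera adjusted p = 0.1824 with an estimated correlation). Of 18 TCR signalling genes Cd3g (0.52) rose and Cd5 and Cd3e fell, and 1 rose and 6 fell when adjusted over the list alone (median -0.13, camera adjusted p = 0.001276, median -0.07 to -0.25 with 1 library left out, and camera adjusted p = 0.1824 with an estimated correlation). Of 11 ILC2 genes 2 fell, 2 also when adjusted over the list alone (median -0.16, camera adjusted p = 0.008489, median 0.04 and camera adjusted p = 0.1271 without D/N440K replicate 2, and camera adjusted p = 0.2177 with an estimated correlation). Of 10 cytotoxic granule genes none passed, nor when adjusted over the list alone (median 0.20, camera adjusted p = 0.00403, median 0.10 and camera adjusted p = 0.1 without D/N440K replicate 1, and camera adjusted p = 0.3626 with an estimated correlation). Of 12 progenitor genes none passed and 3 rose when adjusted over the list alone (median 0.32, camera adjusted p = 0.004143, 0.08485 without +/N440K replicate 1, 0.06368 without D/N440K replicate 1, and camera adjusted p = 0.2177 with an estimated correlation). Of 20 G2 and mitosis genes none passed and 1 rose when adjusted over the list alone (median 0.11, camera adjusted p = 0.004143, 0.09955 without +/N440K replicate 1, median 0.07 and camera adjusted p = 0.129 without D/N440K replicate 2, and camera adjusted p = 0.5037 with an estimated correlation). Of 10 dendritic and MHC II genes none passed, nor when adjusted over the list alone (median 0.15, camera adjusted p = 0.00722, and camera adjusted p = 0.5802 with an estimated correlation), a call lost without D/N440K replicate 1 (camera adjusted p = 0.06368), and without +/N440K replicate 1 the median turned to -0.24 and without +/N440K replicate 2 it rose to 0.94. In lists that were not called, Rag1 rose and Cd8a fell in the pre-TCR and double-positive list, whose median was 0.13 and mean 0.26 while its test pointed down (camera adjusted p = 0.8928). In the type 17 list (median -0.07, camera adjusted p = 0.1839), Ncr1 rose and Il17re fell. Icos (-1.05) fell in the ILC precursor list (camera adjusted p = 0.7207) and Dtx1 (-0.51) in the Notch target list (camera adjusted p = 0.3154). No member passed in the lists of T lineage factors (camera adjusted p = 0.3573) or myeloid genes (camera adjusted p = 0.143). Cd3g, Icos and Dtx1 were each lost without +/N440K replicate 2 (edgeR adjusted p = 0.1304, 0.2117 and 0.1396) and D/N440K replicate 2 (edgeR adjusted p = 0.1958, 0.1741 and 0.497). The mature αβ (camera adjusted p = 0.9478), DNA replication (camera adjusted p = 0.7207), interferon (camera adjusted p = 0.1839), immediate early (camera adjusted p = 0.6419), p53 and BCL2 (camera adjusted p = 0.6419) and ribosomal protein (camera adjusted p = 0.3074) lists were not called. edgeR called 58 of 10910 genes, 31 higher and 27 lower, with 851 at unadjusted p under 0.05. All 58 had groups that did not overlap, against 35.36% of all genes and 33.33% by chance. DESeq2 called 4 genes, among them Plxnd1 (-0.96) and Plcg1 lower and Mtmr9 (1.14) higher. Leaving out 1 library gave 19 to 50 calls, with 19 without D/N440K replicate 1 and 23 without D/N440K replicate 2. Camera called 8 of 20 lists, 5 up and 3 down, and 0 with an estimated correlation (4 at unadjusted p under 0.05) or with fry (4 at unadjusted p under 0.05).

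The comparison of Tcf7 F/F:Vav1-Cre with Tcf7 +/+ addressed the genotype question for Tcf7 at postnatal day 7. Tcf7 counts were higher, 733.1 ± 100 against 572.9 ± 29.2 CPM (0.35 ± 0.125, edgeR adjusted p = 0.0497), a call lost in most alternatives, such as without Tcf7 F/F:Vav1-Cre replicate 1 (0.24, edgeR adjusted p = 0.2372). Rag1 fell from 363.2 ± 50.7 to 0.8317 ± 0.288 CPM (log2 fold change -8.65, edgeR adjusted p = 1.87e-12), and Dntt, the template-independent polymerase of V(D)J joining, from 128 counts to 0, at least 57.8-fold lower. Cd3d fell from 116.4 ± 14.8 to 1.475 ± 0.316 CPM (-6.25 ± 0.308), Cd28 from 130.8 ± 42.3 to 2.04 ± 1.2 (-5.92 ± 0.347) and Sox13 from 238.4 ± 27.9 to 5.61 ± 2.04 (-5.44 ± 0.23). Of 18 TCR signalling genes 12 fell and 6 were not past the test, Themis (-5.43) and Cd6 (-4.00) among those that fell. 13 fell when adjusted over the list alone (median -1.48, camera adjusted p = 6.53e-24, and camera adjusted p = 0.09953 with an estimated correlation). In the pre-TCR and double-positive list 2 genes rose, Cd4 (0.80) among them, and Rag1, Dntt, Rag2, Arpp21 (-5.63), Aqp11 (-2.85), Cd24a (-2.24), Cd8b1 (-1.83), Mns1 (-1.57), Cd8a (-0.97) and Tcf12 (-0.65) fell. Adjusted over the list alone these were 2 and 10 as well (median -1.83, camera adjusted p = 9.28e-13, and camera adjusted p = 0.09953 with an estimated correlation). In the γδ list Maf (0.60) rose, and Trgv2 (-4.84), Tcrg-C4 (-4.04), Tcrg-C2 (-2.30), Sox4 (-2.11), 5830411N06Rik (-2.03), Etv5 (-1.75), Trdc (-1.56) and Sox13 fell. Adjusted over the list alone these were 1 and 8 as well (median -1.66, camera adjusted p = 1.2e-14, and camera adjusted p = 0.1511 with an estimated correlation). In the mature αβ list Foxp3 (5.10), Zbtb7b (1.06), Il6ra (1.01) and Ccr7 (0.99) rose, and Trac (-3.93), Itm2a (-3.08), S1pr1 (-2.47), Trbc1 (-1.06), Klf2 (-0.71) and Cd40lg were among the 7 that fell. The same 4 and 7 passed when adjusted over the list alone (median -0.71, camera adjusted p = 0.01028, and camera adjusted p = 0.1608 with an estimated correlation). Among T lineage factors Tox (0.91), Runx1 (0.38), Ikzf3 (0.35) and Tcf7 rose, and Myb (-3.08), Satb1, Lef1 (-1.09), Tcf12 and Bcl11b (-0.48) fell, and 5 rose and 5 fell when adjusted over the list alone. Their median was 0.01 and their mean -0.42, with a test that pointed down (camera adjusted p = 0.006049, and camera adjusted p = 0.1608 with an estimated correlation). The median changed sign with single libraries, from -0.10 without Tcf7 +/+ replicate 1 to 0.14 without Tcf7 +/+ replicate 2. The Bcl11b call (edgeR adjusted p = 0.0131) was lost without Tcf7 F/F:Vav1-Cre replicate 1 (edgeR adjusted p = 0.096) or replicate 3 (edgeR adjusted p = 0.07497), and Bcl11a (-0.09 ± 0.163, edgeR adjusted p = 0.7276) and Gata3 (0.19 ± 0.147, edgeR adjusted p = 0.3831) did not pass.

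Genes of innate lymphoid cells split in the Tcf7 comparison. Cxcr5 rose from 28.46 ± 2 to 367.5 ± 32.4 CPM (edgeR adjusted p = 1.52e-10). In the type 17 and ILC3 list Cxcr5, Lta (3.19), Batf3 (2.67), Il1rn (1.81), Ccr6 (1.79), Ahr (1.38), Il17re (1.19), Il1r1 (1.17) and Nrp1 (0.51) were among the 10 that rose, and Ncr1 (-1.16), Il17a (-0.89) and Il17f (-0.69) fell, and 11 rose and 3 fell when adjusted over the list alone (median 1.18, camera adjusted p = 4.21e-12, and camera adjusted p = 0.09953 with an estimated correlation). In the ILC2 list Csf2 (3.63), Ptgdr2 (3.06), Nmur1 (2.80), Il2ra (2.77), Il13 (1.94), Il1rl1 (1.34), Hlf (1.22) and Rora (0.81) rose, and Il4 (-1.56), Arg1 (-1.41) and Il9r (-0.97) fell. The same 8 and 3 passed when adjusted over the list alone (median 0.81, camera adjusted p = 1.02e-04, and camera adjusted p = 0.1608 with an estimated correlation). In the ILC precursor list Cxcr5, Ltb4r1 (2.02), Tox2 (1.78), Pdcd1 (1.76), Cxcr6 (0.86), Nfil3 (0.76), Id2 (0.70), Rora and Itgb7 (0.44) rose, and Zbtb16 (-1.99), Zfp683 (-1.89) and Il18rap (-0.40) fell, and 11 rose and 3 fell when adjusted over the list alone (median 0.44, camera adjusted p = 1.03e-04, and camera adjusted p = 0.1608 with an estimated correlation). Zbtb16, which encodes PLZF, fell from 289.4 ± 85.7 to 73.22 ± 5.64 CPM (edgeR adjusted p = 2.19e-07), while Id2 rose from 273.9 ± 35 to 444.9 ± 45.8 (edgeR adjusted p = 9.86e-04). Of 22 NK and ILC1 genes 13 fell and 9 were not past the test, Cd160 (-2.74), Klrc1 (-2.39), Klrk1 (-2.28) and Itga1 (-1.38) among those that fell. 3 rose and 15 fell when adjusted over the list alone (median -1.21, camera adjusted p = 4.15e-09, and camera adjusted p = 0.1657 with an estimated correlation). In the cytotoxic granule list Gzmb (0.54) rose, and Ifng (-2.11), Gzmc (-1.86), Ctsw (-0.88), Serpinb9 (-0.86), Serpinb6b (-0.69) and Nkg7 (-0.65) fell. Adjusted over the list alone these were 1 and 6 as well (median -0.65, camera adjusted p = 0.01987, 0.09409 without Tcf7 +/+ replicate 1, and camera adjusted p = 0.2811 with an estimated correlation).

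Kit rose from 59.17 ± 3.2 to 347.1 ± 19.7 CPM in Tcf7 F/F:Vav1-Cre (2.55 ± 0.147, edgeR adjusted p = 2.03e-09). In the progenitor list Kit, Gata2 (1.32), Nfe2 (1.27), Spi1 (1.08) and Mycn (1.04) rose, and Hmga2 (35 counts against 2, ratio 23.7, interval 6.09 to 203) and Mef2c (-0.82) fell, and 7 rose and 2 fell when adjusted over the list alone (median 0.69, camera adjusted p = 0.02986, median 0.32 and camera adjusted p = 0.1251 without Tcf7 +/+ replicate 2, and camera adjusted p = 0.2811 with an estimated correlation). The Gata2 call was lost without Tcf7 F/F:Vav1-Cre replicate 3 (0.81, edgeR adjusted p = 0.1286). Of the Notch targets Heyl (6.07), Il2ra and Tcf7 rose and Myc (-1.80) fell, and 4 rose and 2 fell when adjusted over the list alone (median 0.35, camera adjusted p = 0.006049, and camera adjusted p = 0.1608 with an estimated correlation). In the B lineage list Bank1 (2.03) rose, and Ebf1 (-3.40), Ms4a1 (-2.78), Pax5 (-2.13), Cd79a (-2.06), Blnk (-0.67) and Ighm (-0.67) were among the 7 that fell. Adjusted over the list alone these were 1 and 7 as well (median -0.67, camera adjusted p = 0.001451, median -1.04 without Tcf7 +/+ replicate 2, and camera adjusted p = 0.2294 with an estimated correlation). Of 13 myeloid genes 7 rose and 6 were not past the test, Cd14 (2.17), Cebpb (1.34), Csf1r (1.27) and Lyz2 (1.07) among those that rose. 8 rose and 1 fell when adjusted over the list alone (median 0.89, camera adjusted p = 0.005348, 0.09839 without Tcf7 +/+ replicate 2, and camera adjusted p = 0.2972 with an estimated correlation). Of 6 mast and basophil genes 5 rose, Cpa3 (3 counts against 58, ratio 14.3, interval 4.65 to 71.3) and Tpsb2 (0 counts against 49, at least 12.1-fold higher, but not past DESeq2) among them. 6 rose when adjusted over the list alone (median 2.16, camera adjusted p = 0.01203, and camera adjusted p = 0.1608 with an estimated correlation). Of 6 stroma genes Pdgfrb (5.91), Krt8 (2.69, and 4.09 without Tcf7 +/+ replicate 2) and Pecam1 (0.82) rose, the same 3 when adjusted over the list alone (median 0.45, camera adjusted p = 2.79e-06, median 0.74 and 0.24 without Tcf7 +/+ replicate 1 and 2, and camera adjusted p = 0.09953 with an estimated correlation), and Epcam did not pass (-0.28, edgeR adjusted p = 0.6698). Among dendritic and MHC II genes Xcr1 (1.49), Cd209a (0.98), H2-Ab1 (0.56), H2-Eb1 (0.52) and Cd74 (0.42) rose and Ccl22 (-0.94) fell. The list was not called (median 0.34, camera adjusted p = 0.114) except without Tcf7 +/+ replicate 1 (camera adjusted p = 0.005735), where Xcr1 lost its own call (edgeR adjusted p = 0.05497).

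Cell cycle genes were lower in Tcf7 F/F:Vav1-Cre, Mki67 falling from 822.8 ± 313 to 404.4 ± 36.7 CPM (log2 fold change -1.03, edgeR adjusted p = 2.5e-04). Of 20 G2 and mitosis genes 14 fell and 6 were not past the test, Kif11 (-1.05) and Top2a (-0.90) among those that fell. 17 fell when adjusted over the list alone (median -0.82, camera adjusted p = 5.33e-07, and camera adjusted p = 0.1608 with an estimated correlation). Of 19 DNA replication genes 10 fell and 9 were not past the test, Rrm1 (-0.96) among those that fell. 16 fell when adjusted over the list alone (median -0.55, camera adjusted p = 4.36e-05, and camera adjusted p = 0.2294 with an estimated correlation). Much of the size of these changes came from Tcf7 +/+ replicate 2. Without it Mki67 stood at -0.58, Kif11 at -0.57, Top2a at -0.50 and the G2 and mitosis median at -0.53. In that fit the lone Tcf7 +/+ library was assumed to vary like Tcf7 F/F:Vav1-Cre. It cannot show whether these falls exceed the spread of the +/+ pair. Of 18 interferon response genes 10 rose and 8 were not past the test, Oas2 (1.33), Usp18 (1.03) and Irf7 (0.83) among those that rose. 11 rose when adjusted over the list alone (median 0.66, camera adjusted p = 4.36e-05, and camera adjusted p = 0.09953 with an estimated correlation). Of the immediate early genes 10 rose, Fosb (1.25), Fosl2 (1.17), Jun (1.12) and Fos (0.65) among them, Nr4a2 (-1.04) fell and 6 were not past the test, and 11 rose and 1 fell when adjusted over the list alone (median 0.54, camera adjusted p = 0.005181, median 0.35 without Tcf7 +/+ replicate 2, and camera adjusted p = 0.4099 with an estimated correlation). Fosb stood at 0.65 in libraries with Y-linked reads only (edgeR adjusted p = 0.4969). Of 7 mitochondrial RNA genes 6 fell, mt-Cytb (-0.72) and mt-Nd2 (-0.84) among them. 7 fell when adjusted over the list alone (median -0.71, camera adjusted p = 0.001704, and camera adjusted p = 0.3152 with an estimated correlation). Without Tcf7 +/+ replicate 2 these stood at -0.36 and -0.40, with a list median of -0.39. Of 31 ribosomal protein genes 4 fell, Rps3 (-0.57, and -0.38 without Tcf7 +/+ replicate 2) among them, and the other 3 were lost without that library (edgeR adjusted p = 0.1978 to 0.5355). 2 fell when adjusted over the list alone (median -0.34, camera adjusted p = 0.006049, 0.06878 without Tcf7 +/+ replicate 2, and camera adjusted p = 0.4362 with an estimated correlation). In the p53 and BCL2 list, not called (median 0.17, camera adjusted p = 0.3371), Bcl2 (1.61), Cdkn1a (1.25) and Bcl2l1 (0.50) rose and Fas (-2.29) and Trp53inp1 (-0.60) fell. Only 1 erythroid gene was tested.

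Among genes of average log2 CPM 3 or more, Eps8l3 rose from 0 to 341 counts, at least 84-fold higher, and Fbxl21 from 1 to 190 counts (ratio 140, interval 24.9 to 5570). Izumo1r fell from 210 counts to 0, at least 94.8-fold lower. edgeR called 2863 of 12366 genes, 1487 higher and 1376 lower, and the groups did not overlap in 2829 of them, against 48.8% of all genes and 20% by chance for 3 libraries against 2. DESeq2 called 1961, and leaving out 1 library gave 1717 (without Tcf7 F/F:Vav1-Cre replicate 3) to 4443 calls (without Tcf7 +/+ replicate 1). Camera called 22 of 24 lists, 10 up and 12 down, 0 held with an estimated correlation (6 at unadjusted p under 0.05), and fry called 18. Sex differed between the groups. Both Tcf7 +/+ libraries had Y-linked reads (316 and 399 CPM) with Xist at 3.41 and 0.558 CPM, whereas Xist stood at 1641, 6.14 and 1423 CPM and Y-linked reads at 0, 310 and 1.09 CPM in Tcf7 F/F:Vav1-Cre. Using libraries with Y-linked reads only, 1 against 2, edgeR called 0 genes (1411 at unadjusted p under 0.05), limma-voom 0 and DESeq2 302, and with sex as a term edgeR called 1112.

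**Figure D2:**
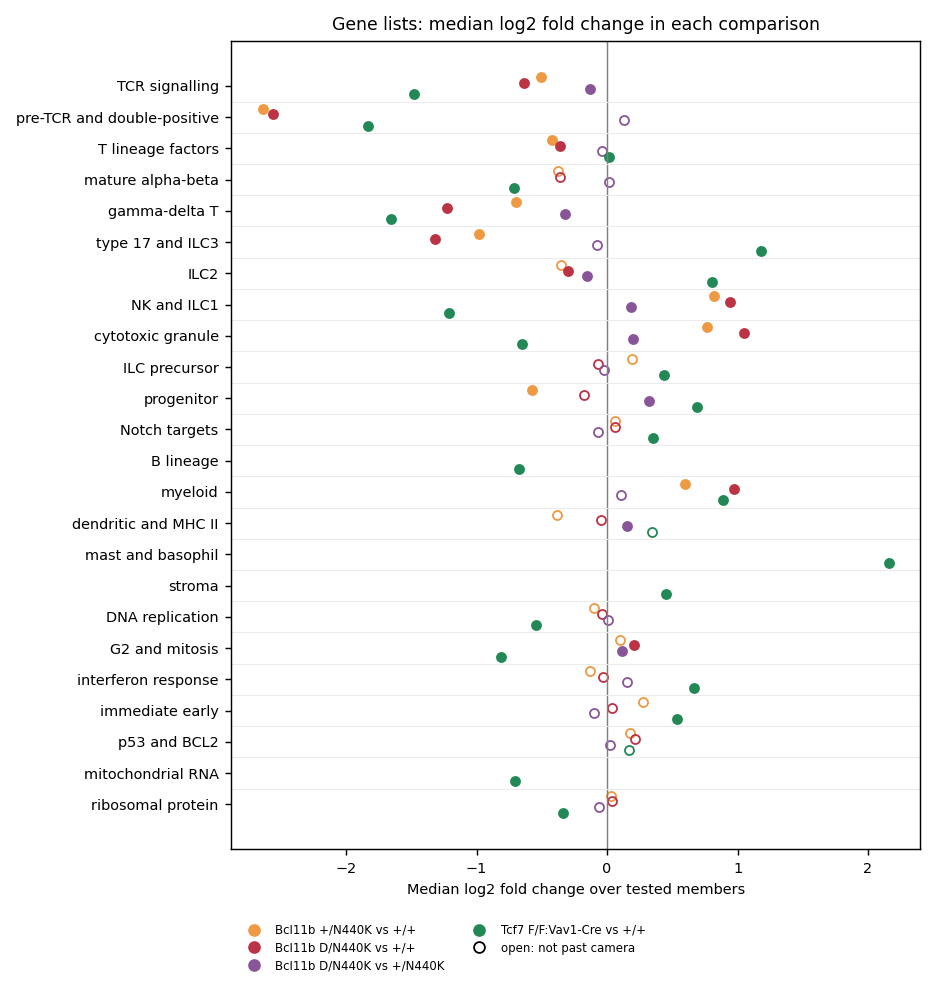
Median log2 fold change over the tested members of each gene list (horizontal axis) in the 4 comparisons, with filled points for lists past camera at adjusted p under 0.05 and open points for the others. The NK and ILC1 list lies at 0.94 in D/N440K and at -1.21 in Tcf7 F/F:Vav1-Cre, and the type 17 and ILC3 list at -1.32 and 1.18.

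Many calls were common to both mutant Bcl11b genotypes. Of the calls in +/N440K and D/N440K, 832 lay in the same direction, 400 higher and 432 lower, and 0 were opposite. Both comparisons use the same +/+ libraries, which alone makes opposite calls rare. In 50 simulations without change that shared +/+ libraries in the same way, the mean and maximum were 0 calls in the same direction. Without change hardly any gene is called, so this 0 cannot show how many shared calls came from the +/+ libraries. The simulations held no deviation of the +/+ pair beyond the fitted spread. Their fold changes correlated at r = 0.806 across genes, which are not independent replicates, against a mean of 0.501 and a maximum of 0.528 in these simulations. Id2, Ncr1 and Eomes rose in both and Rag1, Sox13 and Lef1 fell in both. D/N440K and Tcf7 F/F:Vav1-Cre shared 404 calls of 10531 genes tested in both tables, 184 higher and 220 lower (66.46 and 76.2 expected, Fisher's exact p = 2.28e-41 and 6.03e-54). Rag1, Sox13, Lef1 and Zbtb16 fell and Id2 rose in both. A further 245 lay in opposite directions, 111 higher in D/N440K and lower in Tcf7 F/F:Vav1-Cre (73.55 expected, Fisher's exact p = 6.68e-06) and 134 the other way (68.86 expected, Fisher's exact p = 7.79e-15). Eomes, Ncr1 and Klrk1 rose in D/N440K and fell in Tcf7 F/F:Vav1-Cre, and Il1r1, Il17re, Ccr6 and Cxcr5 did the reverse. +/N440K and Tcf7 F/F:Vav1-Cre shared 332 calls, 141 higher and 191 lower (52.5 and 63.4 expected, Fisher's exact p = 6.22e-30 and 1.1e-49). A further 97 were higher in +/N440K and lower in Tcf7 F/F:Vav1-Cre (58.1 expected, Fisher's exact p = 2.13e-07), and 99 were the other way (57.29 expected, Fisher's exact p = 3.59e-08). Fisher's test also takes genes as independent, which they are not, so its p-values are too small. Calls exceeded expectation in opposite directions as well as in the same direction. An excess alone therefore does not show a shared or an opposed effect.

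**Figure D3:**
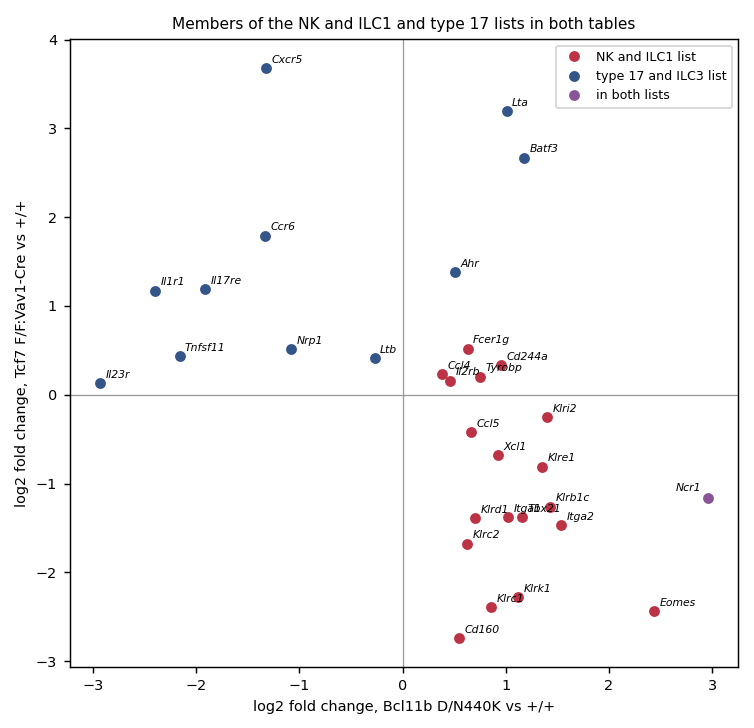
Log2 fold change in D/N440K against +/+ (horizontal axis) and in Tcf7 F/F:Vav1-Cre against Tcf7 +/+ (vertical axis), with points for the members shown by name of the NK and ILC1 list, the type 17 and ILC3 list, and Ncr1, which is in both. Eomes lies at 2.44 and -2.44, and Il1r1 at -2.40 and 1.17.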

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

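The tests of a sex and a depth difference within the Tcf7 +/+ pair, of a smaller share of a T-like cell type, of directions in split Tcf7 libraries, and of the difference between the D/N440K and Tcf7 F/F:Vav1-Cre effects were chosen only after the results were seen.

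The effects of D/N440K and Tcf7 F/F:Vav1-Cre, each against its own +/+ libraries, differed most, of 20 lists tested, in genes of NK cells and of type 17 cells. Eomes differed by 4.86 on the log2 scale (edgeR adjusted p = 3.43e-08), Ncr1 by 4.11 (edgeR adjusted p = 1.04e-09) and Cd160 by 3.29 (edgeR adjusted p = 6.28e-09), all higher in D/N440K and lower in Tcf7 F/F:Vav1-Cre. Cxcr5 (-5.01), Il1r1 (-3.58), Ccr6 (-3.14) and Il17re (-3.11) differed the other way. The median difference of the NK and ILC1 list was 2.23 (0.94 against -1.21), with 16 of 20 members called and camera adjusted p = 9.3e-39 (camera adjusted p = 0.007758 with an estimated correlation). The median difference of the type 17 and ILC3 list was -2.61 (-1.32 against 1.19), with 12 of 13 members called and camera adjusted p = 1.14e-24 (camera adjusted p = 0.007758 with an estimated correlation). The ILC2 list differed by -1.51 and the cytotoxic granule list by 1.13 (camera adjusted p = 0.02011 and 0.02706 with an estimated correlation). In all, 14 of 20 lists were called, and 6 with an estimated correlation. Among those lower in both, the pre-TCR and double-positive list (median difference 0.15, although its test pointed down) had camera adjusted p = 2.5e-04, and 0.02706 with an estimated correlation. The TCR signalling list (0.25) had camera adjusted p = 5.67e-06, and 0.09256 with an estimated correlation. Notch targets differed by -0.62 (camera adjusted p = 4.34e-04, and 0.02707 with an estimated correlation). The γδ list, lower in both, did not pass (0.15, camera adjusted p = 0.5128), nor did the myeloid list, higher in both (-0.08, camera adjusted p = 0.96). Over all genes, edgeR called 1348 of 10531 differences, 676 higher and 672 lower. Mutation, age and table go together in this test, and sex also differed between the Tcf7 groups, so which of them made the difference cannot be seen. The model fitted 1 spread per gene over both tables. Their biological coefficients of variation were 0.0445 (Bcl11b) and 0.122 (Tcf7), so its p-values may not hold for the Tcf7 side.

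The mutant genotypes of Bcl11b also differed from each other, in 58 genes by edgeR (4 by DESeq2). Plcg1 was lower in D/N440K, Hbb-bs was higher, a call lost with DESeq2 (DESeq2 adjusted p = 1), and Bcl11b (-0.21) and Bcl11a (0.43) were not past the test. With estimated correlation camera called 0 of 20 lists (4 at unadjusted p under 0.05).

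In D/N440K, NK and cytotoxic genes were higher and T lineage, double-positive, γδ and type 17 genes lower than in +/+, although 3 of 13 type 17 genes rose and the cytotoxic, T lineage factor and type 17 lists did not pass with an estimated correlation (camera adjusted p = 0.05739, 0.08268 and 0.1617). A loss of a T-like cell type that left the others as they were would raise the others alike. The NK and ILC1 median (0.94, SE 0.182) exceeded the ILC2 median (-0.30, SE 0.463) by 1.24, but the myeloid median (0.97, SE 0.491) rose like that of NK and ILC1 genes. These SE came from the scatter among the genes of a list, taken as independent, which they are not. They do not measure error between libraries. These medians cannot decide the question. The ILC2 list shares Gata3 with the T lineage factors and Ccr4 with the mature αβ list, so fewer T-like cells could lower it too. GC content was argued against, since the NK and ILC1 median kept 98.7% of its size with GC and length offsets. A loss of a T-like cell type, a change of the NK-like cells themselves, of their share, or of transcription under the mutant protein may each underlie the pattern. These stay open, and nothing in the labels tells shares of cells from levels per cell.

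The Tcf7 +/+ libraries differed from each other more than the Tcf7 F/F:Vav1-Cre libraries did, with 4.98 against at most 2.16 chi-square per degree of freedom. These values used library totals scaled by TMM, and totals without TMM gave 4.95 against at most 2.15. Once GC and length trends were removed the +/+ pair stood at 3.43, still 1.82 times the highest other pair (1.88), so these trends may be part of the difference but not all of it. Sex was argued against, as both had Y-linked reads and Xist at no more than 3.41 CPM, and so was depth, with totals 1.02 times apart. Age is given only as postnatal day 7, and a difference in the source or the handling of these libraries stays open, as nothing says whether they came from separate animals. Mki67 (SD 313 around 822.8 CPM) and Zbtb16 (SD 85.7 around 289.4 CPM) varied widely in this pair.

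The genes called between Tcf7 F/F:Vav1-Cre and Tcf7 +/+ were weighed against sex and GC content. Genes called between the Tcf7 F/F:Vav1-Cre libraries without Y-linked reads and 1 +/+ library kept their direction, between the other Tcf7 F/F:Vav1-Cre library and the other +/+ library, in 86.8% of 4036 cases, or 95.7% of 1943 with the +/+ libraries exchanged, against 68.9% and 71.2% of all genes. The median ratio of the tested to the called log2 fold change was 0.444 and 0.923, so the size depended on the +/+ library used. X and Y held 2.69% of called and 2.68% of tested genes, which cannot decide on sex, since a sex difference need not stay on these chromosomes. The directions kept in the splits argue against sex as the main cause of these directions. They leave the sizes open, and Xist itself follows sex. With GC and length offsets 88.5% were called in the same direction, among 3126 calls. Deviations from each gene's mean correlated with GC content at -0.0176 and -0.422 in Tcf7 +/+. In Tcf7 F/F:Vav1-Cre they correlated at 0.119, 0.18 and 0.399. GC trends thus differed along with genotype, and the offsets cannot fully separate them. A biological difference under the Tcf7 genotype, or a cell mixture that differs with it, may remain as a hypothesis.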

How the results depend on the processing

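The tests with GC and length offsets, libraries with Y-linked reads only, sex as a term, recovered reads and crossed pairing were chosen only after the results were seen. Comparisons are in the order +/N440K and D/N440K against +/+, D/N440K against +/N440K, and Tcf7, and the cause of a change was not tested unless stated. DESeq2 called 357, 528 and 4 genes, and 1961 in Tcf7. An absolute log2 fold change of at least 1, a stricter condition by construction, left 435, 594, 21 and 1402. Without a filter 91 genes were called between D/N440K and +/N440K and 1606 in Tcf7. GC and length offsets gave 89 between D/N440K and +/N440K, and the replicate block 37. Sex as a term gave 1112 in Tcf7, and libraries with Y-linked reads alone gave 0 by edgeR (1411 at unadjusted p under 0.05), where a lone Tcf7 F/F:Vav1-Cre library was assumed to vary like the others, 0 by limma-voom and 302 by DESeq2. With estimated correlation camera called 4, 4, 0 and 0 lists (4 at unadjusted p under 0.05 between D/N440K and +/N440K, and 6 in Tcf7), and fry 0 lists between D/N440K and +/N440K (4 at unadjusted p under 0.05).

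Shared calls of +/N440K and D/N440K were 302 by DESeq2 and 333 with the fold condition, those of D/N440K and Tcf7 were 171 and 167, and those of +/N440K and Tcf7 were 127 and 119. Leaving out 1 library, with any lone library assumed to vary like the other groups, gave 703 to 896, 889 to 979, 19 to 50 and 1717 to 4443 called genes (fewest without +/+ replicate 1, D/N440K replicate 1, D/N440K replicate 1 and Tcf7 F/F:Vav1-Cre replicate 3; D/N440K replicate 2 gave 23 in the third, +/+ replicate 1 gave 892 in the second, and 4443 came without Tcf7 +/+ replicate 1). The dendritic and MHC II list, at 0.15 between D/N440K and +/N440K, ranged from -0.24 without +/N440K replicate 1 to 0.94 without replicate 2. The other counts of genes and lists, under RLE, upper-quartile, limma-voom, limma on the authors' CPM and the stricter filter among others, stayed within 1.5 times. Crossed pairing gave 1128 genes in +/N440K, and same-numbered libraries did not deviate alike (r from -0.105 to 0.0127 across genes). At 999381 to 1842717 counts per library, genes of low level were left untested, and folds against 0 to 3 counts are bounds or wide intervals.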

Other observations

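The tests of neighbouring genes were planned, and no tests in this part were chosen only after the results were seen.

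Immunoglobulin heavy chain gamma reads were found in the Tcf7 +/+ libraries, at 158 and 221 CPM, against 0, 0.559 and 2.17 CPM in Tcf7 F/F:Vav1-Cre and 0 in all 6 libraries of the Bcl11b table. Mitochondrial reads made up 0.358 and 0.482% of counts in Tcf7 +/+ and 0.355, 0.301 and 0.273% in Tcf7 F/F:Vav1-Cre. All 6 libraries of the Bcl11b table held both Xist and Y-linked reads. Xist stood at 439 and 497 CPM in +/+, 339 and 371 in +/N440K, and 295 and 362 in D/N440K. Y-linked reads stood at 177 and 197, 154 and 178, and 180 and 182 CPM in the same order. Whether the mix of sexes differed between these groups was not tested.

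Genes called in the Tcf7 comparison lay beside each other more often than by chance. Of 12341 adjacent pairs of tested genes, 656 were both called in one direction, where 1000 shuffles of the calls gave a mean of 332 and a maximum of 390 (permutation p = 0.001, the smallest that 1000 shuffles can give). Pairs that do not overlap in the annotation numbered 493, against a mean of 281. In D/N440K 229 of 10883 adjacent pairs did so, against a mean of 83.4 and a maximum of 116 (permutation p = 0.001), and 182 of those that do not overlap against 71.6. Shared regulation of neighbours, gene families in clusters, and reads that run past a gene's end may each contribute, and were not told apart.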
